A study of Homo sapiens with 4 samples.

How the data were processed

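RNA of subcutaneous tumors was measured on 8 2-colour Agilent whole human genome arrays, 2 for each of 4 lines of H460 titled as holoclones. Per the labels, 7 to 10 tumors per line were grown, total RNA had a RIN above 8, and 2 independent pools (A and B) of 3 to 5 tumors were made per line and for the parental cells. The RNA was amplified with aminoallyl nucleotides and coupled to Alexa Fluor dyes. On the pool A arrays the holoclone sample carried Alexa 647 (red) and the parental sample Alexa 555 (green); on the pool B arrays the dyes were exchanged. All pool A arrays lay on 1 slide and all pool B arrays on the other. A line thus has 2 replicates, the pools, and the same 2 parental pools serve all lines. The title of the 2H3 sample names a holoclone, while its colony morphology is given as mixed; it was analysed as a holoclone line.

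The deposited array files were written by Agilent Feature Extraction 10.7.1.1. Per the file headers they hold, for each spot, intensity values (median pixel brightness of spot and local background, and processed signals), a log10 ratio of red over green, and other columns of 0 or 1 for spots well above background, saturated or not uniform. The files hold no mean signal, so that median signals were used, also where mean signals had been planned for the alternative without background correction. The deposited table of values holds, per the labels, a linear ratio of holoclone over parental for each of 34127 probes and each line, made by the authors by a method the labels do not give. Its log2 values correlated with the line means computed here with r = 0.888 in 2E1, 0.964 in 2H3, 0.897 in 3F1 and 0.850 in 2E7, with slopes of 1.34, 1.15, 1.37 and 1.39.

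Each array has 44495 spots, 1377 of them controls, which were left out. Values were read in R 4.3.3 with the data.table package (version 1.17.8) and processed with limma 3.58.1: background correction by normexp with an offset of 50, loess of the log2 ratio on intensity within each array, the mean over the 10 spots of each of 999 replicated probes, and a change of sign on arrays with the holoclone in green, so that all ratios are holoclone over parental. A probe was kept where Feature Extraction called it well above background on both holoclone arrays of any line or on at least 6 parental channels (24830 probes). Probe names came from the files and a table of current human symbols (assembly GRCh38.p14); 24827 probes (72.7%) carry 19062 symbols and 9300 carry no symbol. The file headers name the assembly hg18 but the files hold no positions, so gene order and chromosome were taken from the table and no coordinates are given. The brightest probe of a gene represented it, and a probe without a symbol stood for itself, which left 20202 genes (15466 with a symbol, 4736 without). No spot was saturated.

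On 7 arrays the median net signal was 242.5 to 292 units in red and 177.5 to 208.5 in green, and on the pool A array of 2H3 908.5 and 442. The precision at this signal was tested on simulated data, with known changes added to unchanged arrays that had the real spread. For 1 line, 68.7%, 86.6% and 100% of changes of 1.5-fold, 2-fold and 4-fold were called; for a difference between 2 lines the shares were 40.3%, 61.2% and 98.5%, for the F test 20.9%, 55.2% and 95.5%, and across lines with the real spread between them 41.8%, 68.7% and 87.9%. Across lines that share only the parental pools' deviations, 78.3% of the calls were false, since that test leaves out the spread of the parental pools.

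Each line was compared with parental tumors by limma (lmFit and eBayes; 4 residual and 3.59 prior degrees of freedom) in a single fit of all 8 arrays, in which the 4 lines share the spread between pools A and B. Differences between lines were contrasts of the same fit, and any difference was an F test of 3 contrasts. For holoclone tumors in general the 4 line means were tested against 0 (3 residual and 1.66 prior degrees of freedom). All p-values were adjusted by the method of Benjamini and Hochberg, with calls at an adjusted p under 0.05. Of the 725 members of 31 gene lists fixed before the files were opened, those measured were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the residuals. Lists with fewer than 3 measured members were not tested. Members were also adjusted over their list alone. Correlations across genes between lines were set against simulated unchanged lines that shared parental deviations as strongly as the arrays of that pair of lines did. Calls shared by the lines were set against a separate simulation, with a correlation of 0.412 for all lines. No fit compares groups of 3 or more samples, so other splits of the samples were not tested.

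Arrays of 1 slide deviated together from their line means, with correlations of 0.241 to 0.559 for the 6 pairs of lines (2E1 and 2H3 0.312, 2E1 and 3F1 0.546, 2E1 and 2E7 0.504, 2H3 and 3F1 0.311, 2H3 and 2E7 0.241, 3F1 and 2E7 0.559). The slide, which the labels also give as the pool, thus pairs the arrays, and fits with the slide as a block were made as well.

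Genes to name were fixed by rule: with a symbol, an adjusted p under 0.05 and the same sign on every array, the 10 highest and 10 lowest per line among those well above background on at least 1 array of each group, up to 3 in each direction that were not above background in a group, ranked by the bound on their fold, the 10 with the smallest F test p, and 2 to 4 members with the smallest p of each list described. Across lines the rule took 12 in each direction; where fewer than 5 passed it named those with the smallest unadjusted p without giving their number, and 5 in each direction were taken after it was seen that none passed. In a line where a gene was not above background in a group its value is given as a bound, or as approximate where it enters a mean or a span over lines. The bound counts the signal of that group as measured, or as the lowest signal well above background on its array where that is higher. It is for the mean of the 2 arrays and allows nothing for their spread, so a single array can lie under it. Where a gene was above background on only 1 of 2 arrays of a group, this is said beside it.

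Other settings, fixed before the files were opened, were no background correction, Feature Extraction's own log ratios, median centring, Aquantile normalization, no filter and a strict filter on dim probes, the slide as a fixed or random block (statmod 1.5.0), probes of a gene averaged or tested singly, an intensity trend with a robust prior, a minimum log2 ratio of 1, the mean of the line coefficients, the deposited table, and each array or line left out in turn. An arm left with 1 array is assumed to vary like the others. Scale normalization between arrays, and the across-line test without single arrays, were added after the data were seen; the estimated correlation was fixed with the tests. Figures were drawn with matplotlib 3.10.9.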

Results

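Gene expression was measured in subcutaneous tumors grown in scid mice, which lack B and T cells, from H460 cells, an established human large-cell lung carcinoma line, and from 4 lines of H460 titled as holoclones. A holoclone is a compact colony whose cells are regarded as stem-like; for 1 of the lines, 2H3, the labels also give a mixed colony morphology, so its origin is not certain. The lines are H460/2E1, H460/3F1, H460/2E7 and H460/2H3, shortened to 2E1, 3F1, 2E7 and 2H3 and called holoclone lines below. Each line gave 2 RNA pools of 3 to 5 tumors, A and B, and each pool was hybridised with a pool of parental H460 tumors on a 2-colour Agilent array, with the dyes exchanged between A and B. The 8 arrays lay on 2 slides, one per pool, so that slide, pool, parental pool and dye orientation cannot be told apart. Between 65.5% and 76.8% of the 43118 probe spots were well above background in either channel on 7 arrays. On the pool A array of 2H3 the shares were 97.4% in red and 95.6% in green. Log2 ratios of the pools A and B of a line correlated across 20202 genes with r = 0.914 in 2E1, 0.745 in 2H3, 0.937 in 3F1 and 0.793 in 2E7; genes are not independent replicates. Ratios are holoclone over parental, errors are limma standard errors, and n = 2 pools per line throughout. The errors of a line rest on a spread shared by the 4 lines, so they do not show how far its own pools disagree. The median absolute difference between pools A and B was 0.189 in 2H3, against 0.107 in 2E1, 0.119 in 3F1 and 0.148 in 2E7.

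The comparison of each line with parental tumors asks which genes mark tumors of lines held to be stem-like. In tumors of 2E1 the amino acid transporter SLC6A14 rose by 4.60 ± 0.14 on the log2 scale, the matrix metalloproteinase MMP10 by 3.76 ± 0.37, the acute-phase protein HP by 3.49 ± 0.37 and the adhesion molecule CEACAM6 by 3.20 ± 0.25. PSCA, S100A7, XDH, BCAS1, SAA2 and CEACAM7 followed, with log2 ratios between 2.81 and 2.94. The mesoderm transcription factor TBXT, also called brachyury, fell by 6.18 ± 0.08. Other strongly lowered genes were ANO3 (-5.23), the coagulation factor subunit F13A1 (-4.70), the guidance cue SEMA3D (-4.63), the cadherin CDH13 (-4.63), CHL1 (-4.54), ESM1 (-4.50), ADGRG2 (-4.45) and neurotensin, NTS (-4.42). OLFML2A fell by 4.91, while a second probe of that gene went the other way. XYLT1 was not well above background in 2E1 tumors and was at least 24.9-fold lower than in parental tumors; RAB3C was at least 9.68-fold and PLA2G7 at least 5.99-fold lower. PIP, IL36B and CCDC190 were not well above background in parental tumors and were at least 2.45-fold, 2.15-fold and 1.86-fold higher in 2E1. Folds given as at least, here and below, are for the mean of both arrays and allow nothing for its error.

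Among the gene lists fixed before the data were examined, 19 of 26 measured epithelial genes rose in 2E1 and 1 fell (21 and 2 adjusted over the list alone). E-cadherin, CDH1, rose by 2.29 ± 0.16, EPCAM by 1.73 ± 0.16, the desmosome protein DSP by 1.32 ± 0.07 and the epithelial splicing regulator ESRP1 by 1.14 ± 0.08. Camera called the list higher (adjusted p = 1.4e-10; adjusted p = 0.426 with an estimated correlation). Of 26 cytokines and NF-kB targets 12 rose and 4 fell (12 and 4 adjusted over the list alone): the acute-phase gene SAA1 rose by 2.05 ± 0.09 and the apoptosis inhibitor BIRC3 by 1.88 ± 0.11, while IL6 fell by 2.44 ± 0.21. That list was called higher (adjusted p = 0.0136; adjusted p = 0.839 with an estimated correlation). Of 25 laminins and integrins 11 rose, among them LAMB3 (1.36 ± 0.11), and 5 fell, among them LAMA1 (-3.92 ± 0.08) and LAMC1 (-1.27 ± 0.10); the counts adjusted over the list alone were 13 and 6. Camera gave adjusted p = 0.0475 for a rise, and adjusted p = 0.676 with an estimated correlation. Of 13 keratinocyte markers 6 rose and 1 fell (6 and 1 adjusted over the list alone), with S100A7 at 2.93 and the cornified envelope gene SPRR1B, above background on 1 of 2 parental arrays, at 0.92 ± 0.08 (adjusted p = 0.0103 by camera; adjusted p = 0.498 with an estimated correlation). Neuroendocrine and neuronal genes fell, 7 of 14 against 2 that rose (8 and 2 adjusted over the list alone). The prohormone convertase PCSK1 fell by 2.21 ± 0.11 and chromogranin A, CHGA, fell by 1.72 ± 0.13 (adjusted p = 0.0137 by camera; adjusted p = 0.426 with an estimated correlation). YAP target genes fell too, 9 of 21 against 2 that rose (10 and 4 adjusted over the list alone), with CCN2 at -2.18 ± 0.11 and CCN1 at -0.94 ± 0.07 but F3, tissue factor, at 0.97 ± 0.07 (adjusted p = 0.0103 by camera; adjusted p = 0.426 with an estimated correlation).

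In total limma called 3762 of 20202 genes in 2E1 at an adjusted p under 0.05, 2067 higher and 1695 lower. Of these, 316 rose and 384 fell at least 2-fold. Without 2E1 replicate A 1290 genes were called and without 2E1 replicate B 1236; without replicate A the cytokine list (adjusted p = 0.251) and the laminin list (adjusted p = 0.0868) were no longer called. A strict filter on dim probes lost both as well (adjusted p = 0.0919 and 0.126). The laminin list was also lost without background correction (adjusted p = 0.0512) and with Agilent's own log ratios (adjusted p = 0.117). Median centring in place of loess left 1606 genes.

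**Figure D1:**
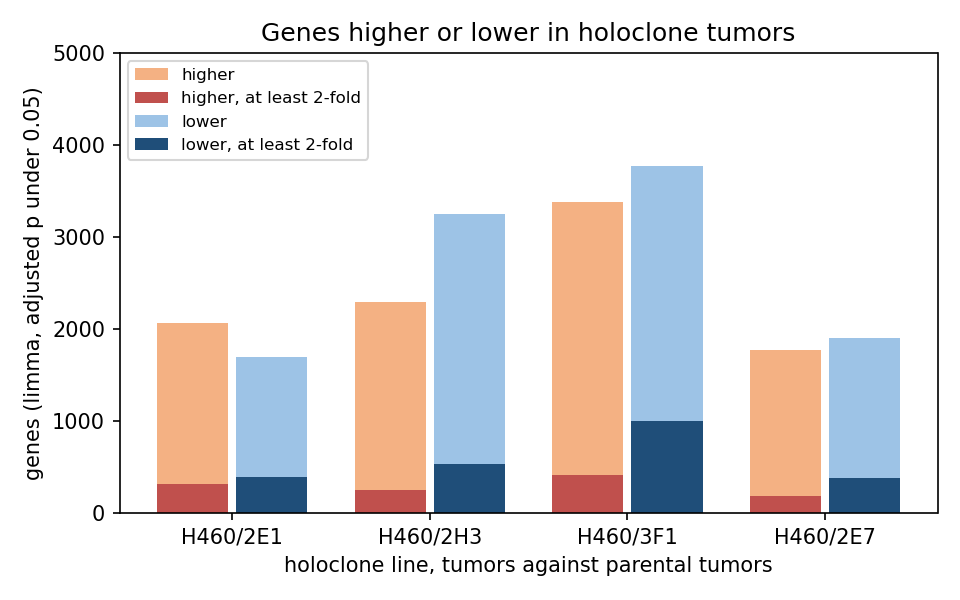
Number of genes higher or lower in tumors of each holoclone line than in parental tumors (vertical axis, genes with limma adjusted p under 0.05); the dark parts of the bars are genes that changed at least 2-fold. The lower bars reach 1695 genes in 2E1 and 3772 in 3F1.

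Tumors of 2H3 had more HP (3.63 ± 0.37) and more of the glucuronosyltransferase UGT2B11 (3.33 ± 0.23) and the hepatokine FGL1 (3.25 ± 0.34). The pluripotency factor SOX2 rose by 3.03 ± 0.16 and the growth factor IGF2 by 2.82 ± 0.22. SPARCL1, MAMDC2, FLI1 and CNTNAP2 followed, with log2 ratios between 2.68 and 3.02. Without 2H3 replicate A FGL1 stood at 3.90, SPARCL1 at 2.43, MAMDC2 at 3.56 and CNTNAP2 at 4.00, and without 2H3 replicate B at 2.60, 3.61, 2.28 and 1.36. DACH2 rose as well and the proteoglycan lumican, LUM, fell, but parental DACH2 and holoclone LUM were above background on only 1 of 2 arrays, so no size is given. The calcium-binding alarmin S100A8 fell by 4.72 ± 0.21. The protease inhibitors SPINK6, SERPINB3 and SERPINB4 had log2 ratios of -4.68, -4.46 and -4.15, and N-cadherin, CDH2, one of -4.37 ± 0.21. On the pool A and pool B arrays of 2H3 CDH2 stood at -3.86 and -4.87, S100A8 at -4.27 and -5.18 and UGT2B11 at 2.81 and 3.85. SOX2 was alike on both, at 3.04 and 3.02. ERC2, TPRXL, the bile acid and drug transporter SLCO1B3 and ANXA10 ranged from -3.97 to -3.89. NDN, ZNF700 and PRG4 were not well above background in 2H3 and were at least 16.1-fold, 4.45-fold and 3.58-fold lower, and ECRG4, ECSCR and PEG10 were at least 2.71-fold, 1.60-fold and 1.57-fold higher than a parental level not well above background. PEG10 was not called with Agilent's own log ratios (adjusted p = 0.0683).

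Of 26 hypoxia genes 13 fell in 2H3 and 0 rose (14 and 1 adjusted over the list alone). TMEM45A fell by 2.74 ± 0.10, and hexokinase 2, HK2, and adrenomedullin, ADM, had log2 ratios of -1.49 ± 0.11 and -1.47 ± 0.14. Of 24 NRF2 targets, a list of antioxidant genes, 11 fell and 0 rose (14 and 0 adjusted over the list alone), with heme oxygenase HMOX1 at -1.51 ± 0.10 and UGDH at -0.61 ± 0.09. Of 34 interferon-stimulated genes 15 fell and 3 rose (16 and 4 adjusted over the list alone), with BST2 at -1.50 ± 0.11, OASL at -1.05 ± 0.13 and SAMD9L at -0.73 ± 0.08. Camera called these 3 lists lower with adjusted p = 0.000882, 0.000882 and 0.0364; with an estimated correlation the values were adjusted p = 0.625, adjusted p = 0.325 and adjusted p = 0.625. All 3 calls were lost without 2H3 replicate B (adjusted p = 0.105, 0.0548 and 0.137), and the interferon list also without 2E7 replicate A or B (adjusted p = 0.0623 each), whose spread enters the same fit, under a strict filter on dim probes (0.063) and with the probes of a gene averaged (0.0592). Without 2H3 replicate A, 5 lists were called.

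Limma called 5542 genes in 2H3, 2295 higher and 3247 lower, of which 250 rose and 532 fell at least 2-fold. The count was 4462 without 2H3 replicate A and 4672 without 2H3 replicate B. Median centring gave 2945 genes, 743 higher and 2202 lower, against a share of 41.4% higher with loess.

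In tumors of 3F1 GABBR2, a subunit of the GABA-B receptor, rose by 4.46 ± 0.07 on the log2 scale. IGF2 (3.27 ± 0.22) rose together with 2 binding proteins of insulin-like growth factors, IGFBP5 (3.80 ± 0.15) and IGFBP7 (3.22 ± 0.13). ELAPOR2, VIT, RNF182, SERPINB2, lipoprotein lipase, LPL, and ADGRV1 had log2 ratios between 3.14 and 3.51. The interleukin receptor IL13RA2 fell by 6.59 ± 0.12, and ANXA10 and LUM had log2 ratios of -5.94 ± 0.15 and -5.71 ± 0.11. UGT1A8 (-5.66), UGT1A6 (-5.27), SERPINB3 (-5.49), SPINK13 (-5.44) and ETNPPL (-5.29) fell as well, and so did KLF5, a transcription factor of epithelial cells (-5.08 ± 0.11). MTTP, MAGEC2 and SLCO1B3 were not well above background in 3F1 and were at least 24.4-fold, 23.3-fold and 19.2-fold lower. TAFA4 and IRF4 were at least 3.01-fold and 2.37-fold higher than a parental level not well above background. MYL1 was higher than such a level too, but the 2 arrays disagreed on its size: its log2 ratio was 2.75 without 3F1 replicate A and 1.05 without 3F1 replicate B. It was not called in the latter case (adjusted p = 0.143) or with Agilent's own log ratios (adjusted p = 0.0732).

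Of the 26 epithelial genes 17 fell in 3F1 and 3 rose (21 and 3 adjusted over the list alone): EPCAM (-4.10 ± 0.16), KRT7 (-2.75 ± 0.14), the protease inhibitor SPINT2 (-2.22 ± 0.12) and the transcription factor ELF3 (-1.82 ± 0.10) were among the lower ones (adjusted p = 1.02e-05 by camera; adjusted p = 0.581 with an estimated correlation). Cytokines and NF-kB targets fell in 12 of 26 cases and rose in 2 (12 and 2 adjusted over the list alone), with IL11 at -2.79 ± 0.15, IL32 at -2.05 ± 0.16 and the prostaglandin synthase PTGS2 at -1.81 ± 0.08 (adjusted p = 0.00295; adjusted p = 0.65 with an estimated correlation). Of 34 interferon-stimulated genes 15 rose and 2 fell (16 and 2 adjusted over the list alone); MX1 rose by 1.66 ± 0.09 and IFI44 by 0.82 ± 0.08, while BST2 fell by 2.78 ± 0.11 (adjusted p = 0.00295; adjusted p = 0.445 with an estimated correlation). Of 19 Notch pathway genes 11 rose and 1 fell (11 and 1 adjusted over the list alone), with the receptors NOTCH4 and NOTCH3 at 1.47 ± 0.08 and 1.33 ± 0.12 (adjusted p = 0.00824; adjusted p = 0.581 with an estimated correlation). Of 37 cell cycle genes 10 rose and 0 fell (9 and 0 adjusted over the list alone): AURKA by 0.75 ± 0.07 and the replication helicase subunit MCM6 by 0.74 ± 0.10 (adjusted p = 0.00868; adjusted p = 0.65 with an estimated correlation). With the slide as a block 16 of them rose and 1 fell.

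NRF2 targets fell in 3F1, 11 of 24 against 3 that rose (15 and 3 adjusted over the list alone), with GPX2 at -3.54 ± 0.26 and HMOX1 at -1.83 ± 0.10 (adjusted p = 0.00824; adjusted p = 0.445 with an estimated correlation). Hypoxia genes fell, 9 of 26 against 2 that rose (9 and 2 adjusted over the list alone), with TMEM45A at -2.66 ± 0.10 and STC2 at -1.51 ± 0.10 (adjusted p = 0.00898; adjusted p = 0.65 with an estimated correlation). Of 12 cancer-testis antigen genes 6 fell and 0 rose (6 and 0 adjusted over the list alone), among them MAGEB2 (-1.63 ± 0.10) and SPANXA1, not above background in 3F1 and at least 10.1-fold lower (adjusted p = 0.00824; adjusted p = 0.581 with an estimated correlation). Under a strict filter on dim probes that list was not called (median -0.13 against -0.26, adjusted p = 0.277). In all, limma called 7152 genes in 3F1, 3380 higher and 3772 lower, with 406 and 998 at least 2-fold. The count was 3660 without 3F1 replicate A and 3450 without 3F1 replicate B, and the cell cycle list was not called without replicate B (adjusted p = 0.172). Median centring gave 3677 genes, and under it the hypoxia and NRF2 lists were not called (adjusted p = 0.0525 and 0.0665).

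Tumors of 2E7 had many of the same leading genes as those of 2E1. HP rose by 3.45 ± 0.37, SLC6A14 by 3.39 ± 0.14, CEACAM6 by 2.46 ± 0.25 and PSCA by 2.42 ± 0.27. SPTSSB (2.79 ± 0.09), the mucin MUC16 (2.54 ± 0.22), the vitamin B12 carrier TCN1 (2.44 ± 0.10), GSTA5, HPR and MGAT4C also rose. MUC16 was not called with Agilent's own log ratios (2.87, adjusted p = 0.056). TBXT fell by 5.55 ± 0.08, and ANO3 and FGF13 had log2 ratios of -5.43 ± 0.18 and -5.10 ± 0.17. OLFML2A, CHL1, SEMA3D, NTS, ESM1, CDH13 and the proton channel HVCN1 had log2 ratios between -4.44 and -3.71. RPE65, PAX3 and ELOVL4 were not well above background in 2E7 and were at least 3.40-fold, 3.05-fold and 2.76-fold lower. RPE65 was not called without 2E7 replicate A (adjusted p = 0.0753). CFAP276, CFAP126 and CDC20B were at least 2.11-fold, 1.72-fold and 1.42-fold higher than a parental level not well above background. CDC20B was not called with median centring (adjusted p = 0.182).

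Epithelial genes rose in 2E7, 14 of 26 against 1 that fell (19 and 1 adjusted over the list alone), with MUC1 at 1.32 ± 0.15, CDH1 at 1.16 ± 0.16 and DSP at 1.09 ± 0.07 (adjusted p = 3.21e-06 by camera; adjusted p = 0.535 with an estimated correlation); CDH1 was just not called without 2E7 replicate A (0.92, adjusted p = 0.0507). Hypoxia genes fell, 13 of 26 against 2 that rose (15 and 2 adjusted over the list alone), with ANGPTL4 at -2.17 ± 0.16 and PDK1 at -1.002 ± 0.098 (adjusted p = 0.000178; adjusted p = 0.589 with an estimated correlation). Neuroendocrine and neuronal genes fell, 7 of 14 against 0 that rose (8 and 0 adjusted over the list alone), with PCSK1 at -1.75 ± 0.11 and CHGA at -1.67 ± 0.13 (adjusted p = 0.00023; adjusted p = 0.33 with an estimated correlation). YAP targets fell, 9 of 21 against 2 that rose (10 and 3 adjusted over the list alone), with CCN2 at -2.51 ± 0.11 and CCN1 at -1.41 ± 0.07 (adjusted p = 0.0012; adjusted p = 0.33 with an estimated correlation). Camera also called lower the 22 angiogenic factors and inhibitors (8 fell, 2 rose; 10 and 4 adjusted over the list alone; CXCL8 -1.06 ± 0.08), the 19 fibroblast markers (7 fell, 2 rose; 8 and 3 adjusted over the list alone; LUM -2.14 ± 0.11 and PDGFRB -1.51 ± 0.10) and the 37 cell cycle genes (2 fell, 0 rose; 2 and 0 adjusted over the list alone; 11 fell and 0 rose with the slide as a block; AURKA -0.55 ± 0.07 and CCNE1 -0.44 ± 0.09). Their values were adjusted p = 0.0324, 0.0324 and 0.0142; with an estimated correlation they were adjusted p = 0.589, adjusted p = 0.45 and adjusted p = 0.611. Without 2E7 replicate B these 3 lists were not called (adjusted p = 0.21, 0.158 and 0.0722), and the angiogenic and fibroblast lists were also lost without 2H3 replicate A or B (adjusted p = 0.0714 and 0.1), without background correction (0.0652 each), with Agilent's own log ratios (0.0832 and 0.0544) and with scale normalization (0.103 and 0.0515). The angiogenic list was further lost with every probe tested (adjusted p = 0.0716), and the fibroblast list under a strict filter (0.0506) and a robust prior with an intensity trend (0.053).

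Limma called 3668 genes in 2E7, 1773 higher and 1895 lower, with 185 and 379 at least 2-fold. The count was 1386 without 2E7 replicate A and 2369 without 2E7 replicate B. Median centring gave 1322, and under it the cell cycle list (adjusted p = 0.224), AURKA (-0.44, adjusted p = 0.253) and CCNE1 (-0.33, adjusted p = 0.388) were not called. CCNE1 was also lost without 2E7 replicate B (adjusted p = 0.128). HP and HPR, SERPINB3 and SERPINB4, UGT1A6 and UGT1A8, SAA1 and SAA2, CEACAM6 and CEACAM7, GSTA5 and its relatives and the MAGE and SPANX genes have near-identical copies, so their probes may read more than 1 gene and their values are uncertain.

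Across the lines, 81 genes rose in all 4 lines and 185 fell in all 4, each at an adjusted p under 0.05 in every line. The higher ones included HP (1.53 to 3.63), the thioredoxin inhibitor TXNIP (0.93 to 1.32), the antisense RNA PAX8-AS1 (1.04 to 1.69) and the pluripotency factor NANOG (0.40 to 0.64), which has near-identical pseudogenes. The lower ones included the cancer-testis antigen genes MAGEC2 (at least 23.3-fold lower in 3F1, where it was not above background) and MAGEA6 (-2.59 to -1.69), the pancreatic protein REG1A (-3.75 to -2.92), the germ-cell RNA-binding protein DAZL (-3.61 to -2.81), the potassium channel KCND2 (likewise at least 14.1-fold lower in 3F1), FGF13 (-5.10 to -1.83) and the cytokine IL11 (-2.79 to -1.60). MAGEC2 in 2H3 and KCND2 in 2H3 and 2E7 were above background on only 1 of 2 holoclone arrays. Some ends of these spans rest on pools that disagreed: HP in 3F1 was at 2.22 without 3F1 replicate B and 0.83 without 3F1 replicate A, MAGEA6 in 2E1 at -2.74 and -0.64 without 2E1 replicate B and A, and REG1A in 2H3 at -2.17 and -3.91 without 2H3 replicate B and A. Independent lists of the same lengths would share 3.45 higher and 4.77 lower genes. The lines were not independent, however. 2E1 and 2E7 shared 1142 higher and 1180 lower calls, and 2H3 and 3F1 shared 1314 and 2146. The figures for independent lists are therefore too low as a comparison. Simulated unchanged lines measured against the same parental pools shared 0 and 0, but had at most 1 call each, so they do not show what the pools add. Part of the excess over independent lists may come from the likeness within these pairs of lines, and part from the shared parental pools.

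A test that takes the 4 line means as the replicates called 0 genes (limma, with 2504 genes at an unadjusted p under 0.05). Because 2E1 and 2E7 were alike (r = 0.845, with 84 genes called between them), the means may hold fewer than 4 independent replicates. The same holds, to a lesser degree, for 2H3 and 3F1 (r = 0.631, with 2076 genes called between them). Standard errors may then be too small in this test. Leading genes in it had an adjusted p between 0.123 and 0.127 and, as the rule for naming them required, the same sign in 4 of 4 lines. They were REG1A (-3.27 ± 0.16, SE, n = 4 lines), DAZL (-3.13 ± 0.16), KCND2 (-3.36 ± 0.22), BATF (-1.33 ± 0.10), PAX8-AS1 (1.45 ± 0.13), TXNIP (1.09 ± 0.08), PLEKHA5 (0.90 ± 0.07), CSTF2T (0.86 ± 0.07) and GABRE (0.79 ± 0.06). Without 2H3 replicate A 9 genes were called, among them KCND2 (adjusted p = 0.0202), DAZL and BATF (0.0225 each), REG1A (0.0419) and PAX8-AS1 (0.0454). Without 2E1 replicate A or 3F1 replicate B 1 gene was called, REG1A (adjusted p = 0.0456 and 0.0427), and without the line 3F1 4 were. Median centring called 3 genes, scale normalization 1, and 0 were called in the values the authors deposited, while the mean of the 4 line coefficients over all 8 arrays, whose spread does not include that between lines, called 7044. Camera on the line means called hypoxia genes (median log2 ratio -0.26), NRF2 targets (-0.12) and cancer-testis antigen genes (-0.16) lower and skeletal muscle markers (0.14) higher, with adjusted p = 0.000163, 0.0265, 0.0265 and 0.0265, though 0 members passed on their own over all genes; adjusted over the list alone 2, 1, 2 and 0 members fell and 0 rose in any. The members with the smallest p were MXI1 (-0.46 ± 0.06) and BNIP3 (-0.40 ± 0.07), TXNRD1 (-0.72 ± 0.08) and HMOX1 (-1.18 ± 0.24), MAGEC2 (-3.73 ± 0.31) and MAGEA6 (-2.16 ± 0.18), and TNNI2 (1.04 ± 0.29) and MYL11, which was near background. The means of KCND2, MAGEC2 and BATF include arrays not above background and are approximate. For all 4 lists adjusted p = 0.985 with an estimated correlation. Tests on the line means leave out the spread of the parental pools, which all lines share. A deviation of those pools could thus shift a list in all 4 lines. The NRF2 list was not called without the line 2H3 or 3F1 (adjusted p = 0.39 and 0.252) or without 2E7 replicate B (0.0665), the muscle list without the line 2H3 (0.123) or 2H3 replicate A (0.127), and the cancer-testis list without the line 3F1 (0.0592). Under a strict filter these 3 lists were not called (adjusted p = 0.0853, 0.67 and 0.399). Nor was the muscle list without background correction (0.0734) or with Agilent's own log ratios (0.0579), nor the cancer-testis list with a robust prior and an intensity trend (0.199).

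**Figure D2:**
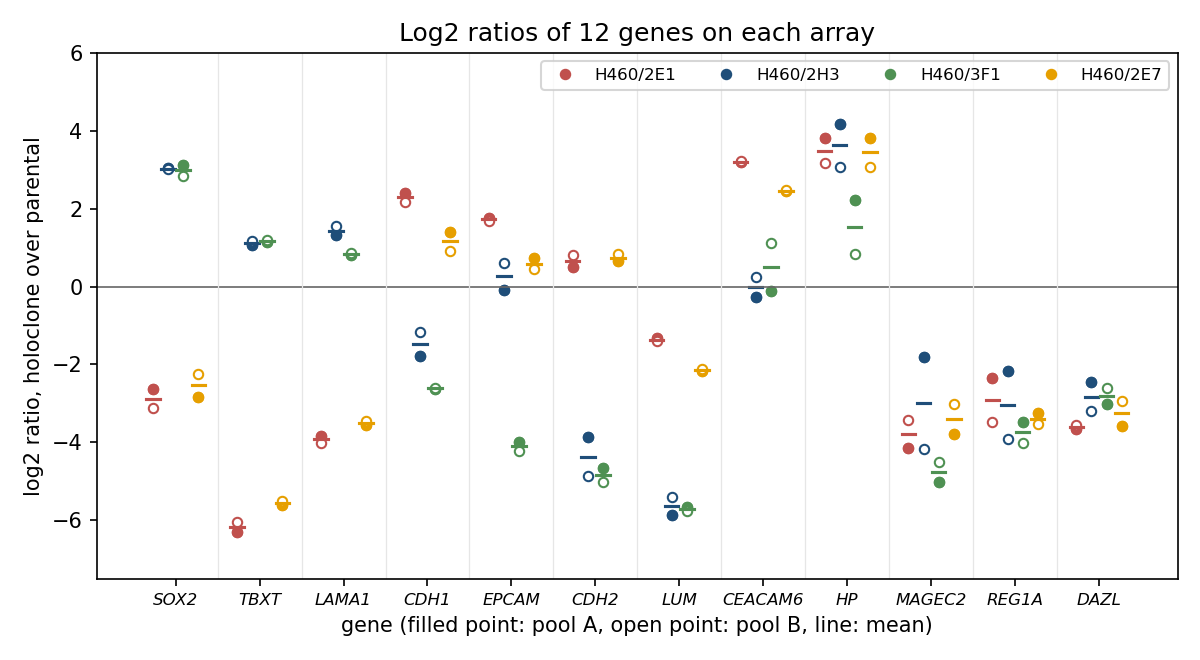
Log2 ratio of holoclone over parental tumors (vertical axis) for 12 genes in the 4 lines; filled points are pool A, open points pool B, and short lines their mean. SOX2 lies at 3.03 in 2H3, 2.99 in 3F1, -2.88 in 2E1 and -2.54 in 2E7, while MAGEC2, REG1A and DAZL are below 0 on all 8 arrays; MAGEC2 in 3F1, and on 1 array in 2H3, is not above background, nor are LUM on 1 array in 2H3 and SOX2 on 1 array each in 2E1 and 2E7, so these points are not exact.

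The comparison between lines asks whether lines of 1 parental culture give alike tumors. They differed at 7012 of 20202 genes (limma F test, adjusted p under 0.05). TBXT was at -6.18 in 2E1 and -5.55 in 2E7 but at 1.12 in 2H3 and 1.17 in 3F1 (± 0.08 each, adjusted p = 2.1e-07). SOX2 was likewise at -2.88 and -2.54 in 2E1 and 2E7 and at 3.03 and 2.99 in 2H3 and 3F1 (± 0.16, adjusted p = 3.2e-06); in the former lines it was above background on only 1 of 2 arrays, so its values there are approximate. LAMA1 (-3.92 and -3.51 against 1.44 and 0.84), the collagen hydroxylase P3H2 (-2.88 and -3.10 against 0.64 and 0.95) and the proteoglycan SPOCK1 (-4.08 and -3.71 against 0.89 and 1.51) were lower in 2E1 and 2E7 in the same way. GABBR2 was at 4.46 in 3F1 and between -1.92 and -1.43 elsewhere. IL13RA2 (-6.59), ADGRL2 (-4.48) and MPZL2 (-3.66) had their lowest values in 3F1, SLCO1B3 was at -3.91 in 2H3 and not above background in 3F1 (at least 19.2-fold lower than parental), and OLFML2A ranged from -4.91 in 2E1 to 1.83 in 3F1. Of 23 stem-cell markers, 8 rose and 5 fell in 2E1, 9 and 4 in 2H3, 11 and 8 in 3F1 and 5 and 7 in 2E7; adjusted over the list alone these were 8 and 7, 9 and 5, 12 and 9, and 7 and 9. Camera called that list in none of the 4 lines (adjusted p = 0.913, 0.282, 0.532 and 0.511 for 2E1, 2H3, 3F1 and 2E7; adjusted p = 0.974, 0.625, 0.65 and 0.611 with an estimated correlation). Besides SOX2, POU5F1 rose in 2E1 (1.44 ± 0.12), CD44 fell in 2H3 (-1.93 ± 0.14) but rose in 2E1 (0.59) and 2E7 (0.51), CD24 rose in 3F1 (1.39 ± 0.09), and KLF4 fell in 2E7 (-1.17 ± 0.09) and 2E1 (-0.97) but rose in 3F1 (0.83).

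Between single lines, 5078 genes differed for 2E1 and 2H3, 6547 for 2E1 and 3F1, 4645 for 2H3 and 2E7, 6183 for 3F1 and 2E7, 2076 for 2H3 and 3F1 and 84 for 2E1 and 2E7. With the slide as a block the counts for the last pairs of lines became 3163 and 222. Agilent's own log ratios gave 0 genes for 2E1 and 2E7 (2123 at an unadjusted p under 0.05), and so did the fits without 2E1 replicate A, 2E1 replicate B or 2E7 replicate A. The count was 16 without 2E7 replicate B, 13 without either 3F1 array and 153 without either 2H3 array. For 2H3 and 3F1 it was 3465 without 2H3 replicate B, 908 without 3F1 replicate A and 800 without 3F1 replicate B. For 2H3 and 2E7 it was 2874 without 2E7 replicate A, for 2E1 and 2H3 2505 and 2646 without 2E1 replicate A and B, and for 3F1 and 2E7 3753 without 3F1 replicate B. For 2E1 and 3F1 it was 4037, 4018 and 4121 without 2E1 replicate A, 2E1 replicate B and 3F1 replicate B. Of the genes that differed for 2H3 and 2E7, 42.6% were higher in 2H3; median centring gave 758 higher and 1748 lower.

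Log2 ratios of 2E1 and 2E7 correlated across genes with Pearson's r = 0.845 (Spearman's rho = 0.687), and those of 2H3 and 3F1 with r = 0.631 (rho = 0.579); simulated unchanged lines with the same parental pools gave 0.492 and 0.299. The covariances were 0.151 and 0.166, and 0.145 and 0.160 after subtraction of the simulated covariances of 0.00640 and 0.00548. The other pairs had r = -0.0954 (2E1 and 2H3), -0.279 (2E1 and 3F1), -0.0344 (2H3 and 2E7) and -0.168 (3F1 and 2E7), against 0.299, 0.535, 0.229 and 0.548 simulated, and covariances less the simulated ones of -0.0232, -0.0791, -0.0116 and -0.0490. Of the called genes, 1142 were higher and 1180 lower in both 2E1 and 2E7, where independent lists would share 181 and 159; 27 were called in opposite directions. For 2H3 and 3F1 the counts were 1314 and 2146, against 384 and 606, with 280 opposite. SLC6A14 and CEACAM6 were among the genes higher in 2E1 and 2E7, and SOX2 and IGF2 among those higher in 2H3 and 3F1, while HP was higher in every line. Each parental pool was 1 RNA, so the controls could not be split further, and part of the excess may come from them.

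Lists of markers of other cell types that a tumor in a mouse might hold gave few calls on these human probes. Host cells are mouse and would be read only by cross-hybridisation, so this says little about host cell content. Fibroblast, muscle and keratinocyte calls are given above. Camera called endothelial (13 genes), myeloid (13), natural killer and lymphocyte (7), erythroid (6) and adipocyte (6) markers in none of the 4 lines. Their lowest adjusted p values were 0.32, 0.112, 0.291, 0.623 and 0.178. Single members moved strongly: S100A8 and S100A9 fell in 2H3 (-4.72 and -3.13) and 3F1 (-2.56 and -2.90), and CD14 rose there (1.59 and 2.00 ± 0.10) and fell in 2E1 (-1.41) and 2E7 (-0.69). Myoglobin, MB, rose in 2E1 and 2E7 (1.59 and 1.43 ± 0.10) and fell in 2H3 (-0.89) and, to below background, in 3F1 (at least 2.46-fold). Among fibroblast markers FAP rose in 2E1 (1.68 ± 0.19) and 2E7 (0.91) and fell in 2H3 (-2.28) and, to below background, in 3F1 (at least 8.74-fold), while PDGFRB rose in 3F1 (2.66 ± 0.10) and fell in 2E1 (-1.86) and 2E7 (-1.51).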

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

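The tests of technical explanations in this part were chosen after the results were seen, except the one on neighbouring genes, which was written down before its value was computed.

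The 4 lines, all set against the same parental tumors, differed from each other by tests of the difference itself. The F test called 7012 genes, and single contrasts called 5078 (2E1 and 2H3), 6547 (2E1 and 3F1), 84 (2E1 and 2E7), 2076 (2H3 and 3F1), 4645 (2H3 and 2E7) and 6183 (3F1 and 2E7). Between the highest and the lowest line TBXT spanned 7.34 on the log2 scale, IL13RA2 7.21, OLFML2A 6.75, GABBR2 6.38, SPOCK1 5.59, LAMA1 5.36, MPZL2 5.18, ADGRL2 4.91 and P3H2 4.05. SLCO1B3 spanned about 5.42, but its lowest value, in 3F1, is not above background, so this span is not exact.

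The likeness of 2E1 to 2E7 and of 2H3 to 3F1 was weighed against 3 technical explanations. Arrays of like lines that share no parental pool, slide or dye orientation still correlated with r = 0.519 or more, so the shared parental RNA cannot be the whole of it. The median of each gene's neighbours on its chromosome, up to 25 on each side, was then subtracted. At least a share of 0.9898 of either correlation was left, so blocks of neighbouring genes do not carry it. A single line hybridised under 2 names does not suit 2H3 and 3F1, whose medians differ by -0.20 on chromosome 9 against at most 0.0869 between the pools of any line; for 2E1 and 2E7, with a largest difference of 0.040 and 84 genes called, it could not be told apart from alike tumors. What remains is consistent with lines that fall into like pairs, but 4 lines cannot show how often that happens.

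On the pool A array of 2H3, 97.4% of spots were well above background in the holoclone channel and 95.6% in the parental channel, both far from the other 7 arrays, which reached 75.5% and 76.8%. The parental channel held the same RNA pool as the other arrays of its slide, where the share was 70.1% (2E1), 69.3% (3F1) and 76.1% (2E7), so the RNA of the 2H3 tumors alone would not give 95.6% there. A brighter background or scanner gain does not suit either: local background lay within 4.5 units of the slide's other arrays, and the 99th percentile of net signal was at most 1.09 times theirs while the 10th percentile was at least 7.43 times theirs. Hybridisation or labelling of this array remains open. Without it, 2H3 rests on 1 array in 1 dye orientation, where a dye effect no longer cancels. Whether the values for 2H3 are safer with or without this array was not tested.

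Fibroblast markers had a median log2 ratio of 0.083 in 2E1, far from the other lines (-0.37 to -0.30), though without 2E7 replicate B the median in 2E7 was -0.045, so that 1 array carries the upper end of that range. In all, 43 groups of values were tested for a far sample and 3 had one, where chance gives about 1 in 20.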

How the results depend on the processing

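Among the alternatives, scale normalization and single arrays left out of the across-line test were chosen after the data were seen. Of 4396 values for 220 named gene results 4341 kept their side of the threshold, 30 were lost and 25 gained. Of 544 values for 28 list results 498 kept it and 46 were lost, and the 199 values for the F test genes all kept it. Direction never turned, but for the leading genes this was largely fixed in advance. They were chosen with the same sign on every array of a line or in all line means. Block and prior settings, and leaving out an array of another line, do not change a gene's ratio in a line. Named results were also picked for their size or p in these data, so these shares say little about other genes.

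A minimum log2 ratio of 1 left 700, 782, 1404 and 564 genes in 2E1, 2H3, 3F1 and 2E7, 2932 by the F test, and 1623 (2E1 and 2H3), 2325 (2E1 and 3F1), 46 (2E1 and 2E7), 783 (2H3 and 3F1), 1392 (2H3 and 2E7) and 2121 (3F1 and 2E7) between lines, fewer by construction. Median centring gave 1606, 2945, 3677 and 1322 genes per line, 3685 by the F test, 2572, 3266, 15, 922, 2506 and 3044 for the same pairs, 3 genes across lines, 10 lists in 2H3 and r = 0.574 for 2H3 and 3F1. Scale normalization gave 3351 genes in 2H3, 131 for 2E1 and 2E7, 1067 for 2H3 and 3F1 and 1 across lines. Feature Extraction's log ratios gave 0 genes for 2E1 and 2E7 and correlations of -0.223 (2E1 and 3F1) and -0.0897 (3F1 and 2E7). The deposited table gave correlations of -0.227 (2E1 and 3F1) and 0.563 (2H3 and 3F1). The slide as a fixed block gave 222 genes for 2E1 and 2E7 and 3163 for 2H3 and 3F1, as a random block 269 for the former; it gave more calls throughout and moved no other count of changed genes per comparison by over 1.5 times; among lists called, cell cycle genes went from 2 to 11 lower in 2E7 and from 10 to 16 higher in 3F1. Every probe tested gave 41 genes for 2E1 and 2E7 and 9 lists in 2H3, no filter 6 lists in 2H3, a strict filter 1 list across lines, and the mean of the line coefficients 7044 genes across lines. With an estimated correlation 0 lists were called in 2E1, 2H3, 3F1, 2E7 and across lines (camera; 3, 1, 2, 3 and 0 at an unadjusted p under 0.05). The cause was not tested for any of these but the minimum log2 ratio.

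Without 1 array at a time the counts ranged over 1236-4654 in 2E1, 4321-5437 in 2H3, 3450-8213 in 3F1, 1386-4701 in 2E7, 0-9 across lines and 4736-8407 for the F test. Between lines they ranged over 2505-5103 (2E1 and 2H3), 4018-7645 (2E1 and 3F1), 0-153 (2E1 and 2E7), 800-3465 (2H3 and 3F1), 2874-4867 (2H3 and 2E7) and 3753-7226 (3F1 and 2E7). Lists called ranged over 6-7 in 2E1, 0-5 in 2H3, 7-8 in 3F1, 4-8 in 2E7 and 3-5 across lines. Correlations ranged over 0.779 to 0.839 (2E1 and 2E7), 0.554 to 0.628 (2H3 and 3F1), -0.114 to -0.0612 (2E1 and 2H3), -0.301 to -0.247 (2E1 and 3F1), -0.0570 to -0.00439 (2H3 and 2E7) and -0.207 to -0.104 (3F1 and 2E7). Aquantile normalization leaves the ratio of each probe as it is, though the probe that is brightest for a gene can change. Block and prior settings do not enter correlations, so these gave no value, and the random block was not run for lists. Signal over background limits the dim genes: between 65.5% and 76.8% of spots were well above background on 7 arrays.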

Other observations

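The tests on whole chromosomes in this part were chosen after the data were seen.

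Genes of a mesenchymal state moved in both directions. Of 25 measured, 5 rose and 4 fell in 2E1, 6 and 12 in 2H3, 9 and 10 in 3F1 and 2 and 8 in 2E7 (6 and 4, 6 and 12, 11 and 10, and 4 and 8 adjusted over the list alone), and camera called the list in no line (lowest adjusted p = 0.0886 in 2E7). N-cadherin, CDH2, fell in 2H3 (-4.37 ± 0.21, n = 2 pools) and 3F1 (-4.84 ± 0.21), and the collagen crosslinker LOX fell there too (-1.05 and -2.18 ± 0.09), as did the transcription factor SNAI2 in 3F1 (-2.05 ± 0.09). In 2E1 and 2E7 the transcription factor TWIST2 (-2.55 and -2.22 ± 0.15) and TGFBI (-1.93 and -1.76 ± 0.12) fell, while CAV1 rose (0.96 and 0.83 ± 0.08); CAV1 fell in 2H3 (-1.07) and 3F1 (-0.61).

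Extracellular proteases and their inhibitors also moved both ways without a call by camera (lowest adjusted p = 0.473): 13 of 26 rose and 9 fell in 2E1, 5 and 10 in 2H3, 5 and 10 in 3F1 and 5 and 8 in 2E7 (13 and 9, 5 and 11, 5 and 11, and 5 and 8 adjusted over the list alone). The metalloproteinase inhibitor TIMP3 fell in 2E1 (-2.91 ± 0.17) and 2E7 (-2.77), the plasminogen activators PLAT in 2H3 (-1.88 ± 0.13) and PLAU in 3F1 (-1.95 ± 0.09), and SERPINB2, an inhibitor of the latter, rose in 3F1 (3.29 ± 0.09). Of 26 p53 target genes 4 rose and 1 fell in 2E1, 1 and 10 in 2H3, 4 and 6 in 3F1 and 8 and 0 in 2E7 (4 and 2, 1 and 12, 5 and 7, and 10 and 4 adjusted over the list alone), again without a call (lowest adjusted p = 0.134). Camera called no list in any line for Wnt, Hedgehog, ABC transporter, antigen presentation, unfolded protein and amino acid stress, sterol and fatty acid synthesis or drug metabolism genes; the lowest adjusted p values were 0.0812, 0.0761, 0.315, 0.139, 0.0743, 0.32 and 0.175. The death receptor FAS, a p53 target, fell in 2H3 (-1.02 ± 0.08) and 3F1 (-0.92) and rose in 2E1 (0.50) and 2E7 (0.45).

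Genes of chromosome 3 were lower as a whole in 2 lines. Their median log2 ratio over 848 genes was -0.31 in 2H3 and -0.31 in 3F1, with 81.0% and 82.2% of the genes below 0, against 0.10 in 2E1 and 0.10 in 2E7, which also lay beyond all sets of genes described next. In 2H3 and 3F1, sets of genes of other autosomes matched on brightness never went below -0.056 in 1000 draws. The permutation p was 0.000999, the smallest the draws can give (adjusted p = 0.004 over 22 autosomes and 4 lines). Genes were drawn singly, so this p does not measure the spread between pools or the correlation of neighbouring genes. In 8 consecutive segments, from CHL1 to ANKRD18DP in the gene order of GRCh38.p14, the median was at most -0.24 on all 4 arrays of these lines, and without the 53 and 81 genes under -1 the medians still reached -0.27 or less. This is consistent with a lower dosage of the whole chromosome in 2H3 and 3F1 than in the parental tumors, a hypothesis that RNA alone cannot settle.

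Less the median of all autosomal genes, the chromosome 3 medians were -0.28 in 2H3 and -0.30 in 3F1, and under other processing -0.33 to -0.23 and -0.37 to -0.23. In 3F1 chromosome 9 stood at 0.18 on that scale (0.11 to 0.24 under other processing) and chromosome 10 at -0.17 (-0.20 to -0.12). On chromosome 12 the values were -0.10, -0.14, -0.14 and -0.13 in 2E1, 2H3, 3F1 and 2E7. Before that subtraction, 5, 4, 10 and 4 of 22 autosomes lay beyond all matched sets in 2E1, 2H3, 3F1 and 2E7. Of these, 0, 2, 4 and 1 had a median over 0.1 in size. Autosome medians differed by up to 0.0869 between the pools of a line, so the smaller shifts are uncertain.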
